A study of Mus musculus with 24 samples.

How the data were processed

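The data are RNA sequencing libraries of microglia, the resident macrophages of the brain, sorted from whole mouse brain (C57BL/6) as Ly6C-negative, CD11b-positive and Fcrls-positive cells. Per the labels' protocols, 1000 cells were lysed for each library and libraries were made by Smart-Seq2, a full-length method that amplifies complementary DNA and carries neither molecular identifiers nor strand. The 24 libraries analysed here fall into 8 groups given by the labels: female or male, wild type (WT) or neuroligin-4 knockout (NL4-/-), and control or phagocytosis. Each of the 4 control groups has 2 libraries and each of the 4 phagocytosis groups has 4. The series' design text calls the samples biological replicates and states 2 for controls and 5 for a phagocytosis group, so the fifth is not analysed here. The labels do not say what was taken up in the phagocytosis groups, or whether it was taken up in the animal or in culture.

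The deposited files hold, for each library and each of 116945 transcripts, a length, an effective length, an expected count of reads and a relative abundance headed TPM. Per the file headers these are the columns that the quantifier salmon and similar tools write; the quantifier's version, its index, the aligner and the read filters are not given in the sources used here. The authors' expected counts of reads are not normalised and need not be whole, because reads shared by several transcripts are divided among them; they were the input to every test. The authors' TPM, which are divided by effective length and scaled to the same sum in each library, were used together with the deposited effective lengths only for an alternative with length-scaled counts.

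Transcript identifiers were matched to the GENCODE mouse annotation at hand (vM21, genome build GRCm38): 116023 matched, 99.67% of them with the same version, and 922 did not. The unmatched transcripts held 0.274 to 0.379% of a library's reads and were left out. Expected counts were summed over the transcripts of each gene and rounded to whole numbers, which gave 35519 genes, 26375 of them with a read in at least 1 library. The transcript set held 0 transcripts of Nlgn4l, the gene knocked out in these mice, and 0 of Xist and Malat1, so neither the knockout nor Xist could be read from these values and they are not analysed here. Sex labels were checked with the Y-linked genes Ddx3y and Eif2s3y. Total expected counts ran from 421107 to 1013797 per library, so a gene at 10 CPM (its reads scaled to a library total of 1e6) had about 4 to 10 reads and low genes are measured coarsely. Intervals and floors cover counting error only, because reads copied by amplification without molecular identifiers are not independent molecules.

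Genes were tested with edgeR 4.0.16 (quasi-likelihood F test with robust dispersions) on counts with TMM normalisation, after edgeR's expression filter by group with a minimum count of 10, which left 9803 genes. All 24 libraries entered 1 fit with 8 group means and no covariate, so that groups of 2 shared their estimate of the spread with groups of 4. The common dispersion was 0.0812, a biological coefficient of variation of 0.285. P-values were adjusted by Benjamini-Hochberg over the genes tested in a comparison, with a threshold of 0.05. Log2 fold changes carry edgeR's prior count of 0.125 and are given with a standard error (SE) worked back from the fold without that prior count and the F statistic. CPM are TMM-normalised and given as mean and standard deviation (SD). Sums of Y-linked genes and of cell markers, and the marker values set beside those sums, are instead scaled to the library total alone. There were 19 comparisons: genotype within each sex and state, phagocytosis against control within each sex and genotype and as the mean of the 4 sex and genotype groups, sex within each genotype and state, and 6 interactions. For a gene with 0 reads in a group the fold is a bound from a floor of 3 counts over the group; with 1 to 3 reads the ratio of pooled reads is given with its exact 95% interval.

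The genes named follow a rule fixed before the data were examined. In each comparison it takes up to 6 genes in each direction with the largest fold among those past the threshold, with at least 5 CPM in the higher group and no overlap between the libraries of the 2 groups. From each gene list it takes up to 4 members with the smallest adjusted p, or up to 2 where none passed, and where fewer than 3 genes passed a comparison it takes the 3 with the smallest p. Predicted genes and pseudogenes were counted but not named. The few genes named outside the rule are identified as such where they appear.

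The gene lists, also fixed before the data were examined, covered homeostatic microglia, neurodegeneration-associated microglia, interferon response, inflammatory cytokines and NF-kB targets, antigen presentation, uptake receptors and opsonins, lysosome, cholesterol synthesis and uptake, lipid efflux and storage, oxidative phosphorylation, glycolysis and hypoxia response, purinergic signalling and ion channels, TGF-beta signalling, proliferation, immediate early and dissociation-stress genes, unfolded protein response and ATF4 targets, cytosolic ribosomal proteins and mitochondrially encoded mRNAs. Markers of neurons, astrocytes, oligodendrocytes, endothelial and mural cells, border-associated macrophages, monocytes, neutrophils, lymphocytes and erythroid cells were listed as well. A list of neuroligins and neurexins had 0 of 6 annotated members past the filter and could not be tested. The other 27 lists were tested two-sided with camera (limma 3.58.1) at a preset correlation of 0.01 between genes and adjusted by Benjamini-Hochberg over the lists of a comparison. Camera with an estimated correlation and fry were alternatives. Across the 19 comparisons camera called 99 lists, of which 16 also passed with an estimated correlation, 29 with fry and 92 with the replicate number as a block.

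Before use the test was checked on negative binomial counts simulated from the real genes' average levels and dispersions and the real library sizes. In each comparison 100 genes were changed 2-fold and 100 were changed 4-fold, drawn from genes with at least 5 expected reads in a library of median size, so the recovery does not describe lower genes. Every gene recovered had the right sign. For NL4-/- against WT in female controls it recovered 7 and 50 of them with 1 other gene called among 9759 genes run. In female phagocytosis libraries it recovered 43 and 79 with 6 others among 9751. For phagocytosis against control in female WT it recovered 17 and 61 with 9 others among 9752, and for the mean of the 4 groups 74 and 93 with 12 others among 9754. For the genotype by sex interaction in phagocytosis it recovered 5 and 46 with 4 others among 9752.

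Library measures were compared by exact two-sided permutation tests, adjusted by Benjamini-Hochberg over 78 tests; the shares of reads on ribosomal protein genes, satellite-like genes and chemosensory receptors were added to the measures planned. Between pairs of replicates the chi-square per degree of freedom of their counts lay between 2.59 and 16.9, more than counting noise alone gives, so none was a second copy of the same counts. Repeats of 1 sample amplified apart can also exceed counting noise, so this does not show that the libraries are separate samples; each was counted once because the series' design text calls them biological replicates. Alternatives set before the data were examined were size factors by the relative log expression method (RLE), no filter on low counts, a filter of 5 CPM in 4 libraries (11767 genes), length-scaled counts, the replicate number as a block, a fit of only the groups compared, DESeq2 1.42.0, genes of the X and Y chromosomes left out of a count, and each library left out in turn. Alternatives added after seeing the data concerned transcripts of satellite repeats and the numbering of the phagocytosis libraries. A gene was called satellite-like when at least 30% of the 12-base words of one of its transcripts occur in the mouse major satellite monomer or its reverse complement; 12 genes were. The monomer sequence was written from general knowledge and was not among the reference files, and the gene lists were likewise written from general knowledge. Scripts ran in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.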

Results

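RNA was measured in 24 libraries of 1000 sorted microglia each, from female and male mice that were WT or lacked neuroligin-4, a synaptic adhesion protein (NL4-/-). Each sex and genotype had 2 control and 4 phagocytosis libraries. Total expected reads per library ran from 421107 (male NL4-/- control 2) to 1013797 (female WT phagocytosis 1). Between 11582 (female WT phagocytosis 2) and 15156 genes had a read in a library. The Y-linked genes Ddx3y and Eif2s3y together had 0 to 2 reads in every library labelled female and 7 to 37 in every library labelled male. With Kdm5d and Uty, which also had reads in female libraries, the 4 Y-linked genes summed to 13 to 51 reads in females (at most 80.2 CPM) and 50 to 122 in males (at least 92.5 CPM). All p-values from edgeR, camera and DESeq2 are two-sided, and adjusted p are by Benjamini-Hochberg.

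Libraries differed in composition between the states. Cytosolic ribosomal protein genes took 3.82% ± 0.647 (SD, n = 16) of the reads of phagocytosis libraries and 2.60% ± 0.372 (SD, n = 8) of those of control libraries (exact permutation test, adjusted p = 0.00435 over 78 tests). Chemosensory receptor genes took 0.479% ± 0.120 and 0.735% ± 0.239 (exact permutation test, adjusted p = 0.0378). Transcripts built of the mouse major satellite repeat, led by Gm10800 (chromosome 2, 98666547 to 98667301), took 6.30% ± 3.73 and 13.7% ± 7.53. This did not pass over the 78 tests (exact permutation test, p = 0.00353, adjusted p = 0.0917). Many of the 78 could not pass, since the smallest p possible was 0.333 for 2 against 2 libraries and 0.0667 for 4 against 2. The adjusted p is therefore not read as a lack of difference in satellite share. The satellite share passed 20% in female NL4-/- control 1 (22.2%), male WT control 2 (23.3%) and male NL4-/- control 1 (21.5%). Across all 24 libraries the satellite and receptor shares had a Pearson r of 0.649 (permutation p = 0.00081, adjusted p = 0.00486 over 6 relations) and a Spearman rho of 0.561 (permutation p = 0.00553, adjusted p = 0.0166). Without the 2 libraries farthest from the median r was 0.529. Within states the coefficients were also positive but did not pass. In the controls r was 0.522 (exact permutation p = 0.187), rho 0.286 and r without 2 libraries 0.434, and in the phagocytosis libraries r was 0.362 (permutation p = 0.167), rho 0.497 (permutation p = 0.0515) and r without 2 libraries 0.517 (permutation p = 0.0593).

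Phagocytosis libraries were compared with control libraries as the mean of the 4 sex and genotype groups (16 against 8 libraries), which asks what differed between the states irrespective of sex and genotype. Plin2 (chromosome 4, 86648386 to 86670060), which coats lipid droplets, rose from 66.3 ± 21.7 to 535 ± 150 CPM (log2 fold change 3.05 ± 0.181 SE, adjusted p = 2.9e-12). Fth1, the heavy chain of the iron store ferritin, rose from 1963 ± 340 to 7990 ± 2616 CPM (2.02 ± 0.182, adjusted p = 4.26e-08). The intermediate filament gene Vim rose from 10.4 ± 5.06 to 265 ± 128 CPM (4.66 ± 0.411, adjusted p = 4.73e-07). The lysosomal protease gene Ctsb rose from 3360 ± 486 to 6743 ± 902 CPM (1.01 ± 0.103, adjusted p = 7.99e-08). The transcription factor gene Mef2a fell from 177 ± 50.7 to 109 ± 15.9 CPM (-0.66 ± 0.122, adjusted p = 0.0005), and Tgfbr1, a receptor for TGF-beta, fell from 211 ± 38.9 to 122 ± 35.1 CPM (-0.77 ± 0.167, adjusted p = 0.00265). In all 1332 genes passed, 824 up and 508 down, of 9803 tested with edgeR, and DESeq2 called 1528. Among named genes that passed, 70 of 82 also passed with any library left out. The count was 781 without female WT control 2, the lowest with 1 library left out, and 782 with phagocytosis numbers 3 and 4 only. It was 410 (389 of them among the 1332 genes above) without the 3 control libraries over 20% satellite-like, and 53 of the 82 named genes then passed.

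**Figure D1:**
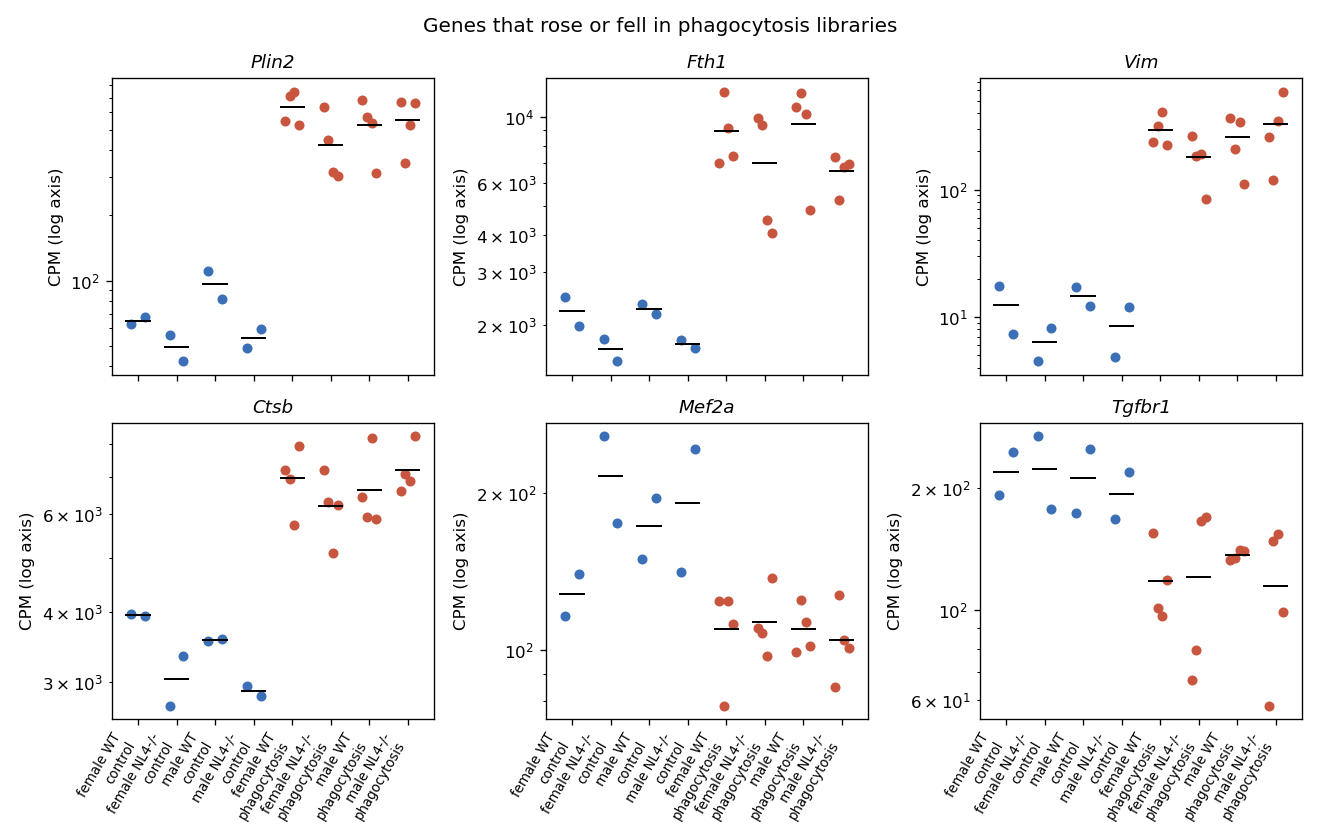
TMM-normalised CPM (log axis) of Plin2, Fth1, Vim, Ctsb, Mef2a and Tgfbr1 in each of the 24 libraries by sex, genotype and state, with a point per library and a line at each group mean. Mean Plin2 was 535 CPM in phagocytosis and 66.3 CPM in control libraries, and mean Mef2a was 109 and 177 CPM.

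Besides Vim, 5 genes made up the largest increases by the naming rule. Il1rn, which encodes the antagonist of the interleukin-1 receptor, rose from 25.6 ± 22.5 to 736 ± 447 CPM (log2 fold change 5.00 ± 0.607, adjusted p = 4.04e-05). Acod1, which makes itaconate, rose from 1.18 ± 1.55 to 53.4 ± 45.7 CPM (adjusted p = 0.00236). The interferon-inducible gene Ifi211 rose from 1.47 ± 2.30 to 35.3 ± 23.1 CPM (adjusted p = 0.000169). Ass1, an enzyme of arginine synthesis, rose by 4.57 ± 0.597 (adjusted p = 2.55e-05), and Ptges, which makes prostaglandin E, rose by 4.44 ± 0.646 (adjusted p = 0.000199). Decreases by the rule were smaller: apart from the olfactory receptor gene Olfr102 (28.5 ± 14.7 to 4.21 ± 5.04 CPM, adjusted p = 0.00069) they lay between the values for Man2a2 (-0.69 ± 0.151, adjusted p = 0.00236) and Nav3 (-0.54 ± 0.105, adjusted p = 0.000845). Mycbp2, a ubiquitin ligase gene, fell from 163 ± 14.6 to 107 ± 18.3 CPM (adjusted p = 0.000182).

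Of the homeostatic microglia genes, 16 of 30 tested fell and 0 rose (27 and 1 adjusted over the list alone), with a median log2 fold change of -0.556 (camera adjusted p = 8.36e-13, adjusted p = 0.148 with an estimated correlation). Besides Mef2a and Tgfbr1, Sall1, a transcription factor of microglial identity, fell by 0.52 ± 0.117 (SE, adjusted p = 0.0035) and Rnase4 fell by 0.72 ± 0.165 (adjusted p = 0.00482). Values were also looked up, after the results were seen, for genes outside the naming rule. Csf1r, the receptor on which microglial survival depends, fell by 0.58 ± 0.163 (adjusted p = 0.0176), whereas P2ry12 (-0.81 ± 0.33, adjusted p = 0.123), Tmem119 (-0.52 ± 0.189, adjusted p = 0.0744) and Cx3cr1 (-0.34, adjusted p = 0.0832) did not pass. Phagocytosis libraries numbered 1 and 2 stood apart from those numbered 3 and 4 in these genes: over the 4 groups the list's median difference between them was -0.498, from -0.817 in female NL4-/- to -0.0136 in female WT.

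Of the genes that rise in neurodegeneration-associated microglia, 26 of 34 rose and 0 fell (28 and 1 adjusted over the list alone, median 1.38, camera adjusted p = 1.1e-27, adjusted p = 0.000119 with an estimated correlation). With Fth1 and Ctsb these included Cybb, a subunit of the phagocyte oxidase, which rose from 9.73 ± 7.70 to 67.6 ± 25.4 CPM (adjusted p = 4.26e-08), and the chemokine gene Ccl4, which rose from 56.5 ± 17.3 to 499 ± 197 CPM (adjusted p = 7.43e-07). Looked up after the results were seen, the lipoprotein gene Apoe rose by 1.28 ± 0.313 (SE, adjusted p = 0.0116) and Spp1, or osteopontin, by 2.98 ± 0.68 (adjusted p = 0.00773). Of the lipid efflux and storage genes, 10 of 22 rose and 0 fell (12 and 1 adjusted over the list alone, median 0.389, camera adjusted p = 8.58e-08, adjusted p = 0.00067 with an estimated correlation). Lpl, a lipoprotein lipase, rose from 148 ± 70.3 to 708 ± 312 CPM (adjusted p = 3.27e-05), and Nceh1, a cholesterol ester hydrolase, by 1.48 ± 0.226 (adjusted p = 4.1e-05). No cholesterol synthesis or uptake gene of 21 passed (camera adjusted p = 0.799); Tm7sf2 had -0.52 ± 0.274 (adjusted p = 0.217).

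Of the interferon response genes, 25 of 31 rose and 0 fell (29 and 0 adjusted over the list alone, median 2.17, camera adjusted p = 3.21e-23, adjusted p = 0.125 with an estimated correlation). Bst2, which tethers viruses at the membrane, rose from 145 ± 43.4 to 458 ± 187 CPM (adjusted p = 0.000453), Rtp4 rose by 2.43 ± 0.397 (SE, adjusted p = 0.000189), and Zbp1, a sensor of nucleic acids, by 2.84 ± 0.499 (adjusted p = 0.000668). Between phagocytosis libraries numbered 1 and 2 and those numbered 3 and 4 the median difference of this list over the 4 groups was 0.885, from 1.69 in female NL4-/- to -0.383 in female WT. Of the cytokine and NF-kB genes, 9 of 24 rose and 3 fell (13 and 3 adjusted over the list alone, median 0.452, camera adjusted p = 0.000238, adjusted p = 0.304 with an estimated correlation). The median difference of this list between the same numbered libraries was 0.213 over the 4 groups, from 0.647 in male NL4-/- to -0.0799 in female WT. The chemokine gene Ccl5 rose from 33.7 ± 50.5 to 657 ± 798 CPM (adjusted p = 0.00119), Cxcl16 rose by 1.41 ± 0.184 (adjusted p = 9.68e-06), and the cytokine gene Il1a fell by 0.83 ± 0.188 (adjusted p = 0.0035). Of the antigen presentation genes, 6 of 19 rose (7 up and 1 down adjusted over the list alone, median 0.436, camera adjusted p = 0.0216, adjusted p = 0.468 with an estimated correlation), among them the class I gene H2-D1 (0.71 ± 0.155, adjusted p = 0.00258) and its regulator Nlrc5 (1.73 ± 0.397, adjusted p = 0.00509).

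Uptake receptors moved both ways. Of 37 genes 12 rose and 5 fell (13 and 9 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.123). C3ar1, a complement receptor, rose from 392 ± 83.8 to 828 ± 181 CPM (adjusted p = 2.51e-06), the scavenger receptor gene Cd36 rose from 4.09 ± 5.15 to 26.2 ± 15.7 CPM (adjusted p = 4.24e-05), and Msr1, another scavenger receptor, by 2.09 ± 0.311 (SE, adjusted p = 0.000227). Of the lysosome genes 9 of 42 rose and 1 fell (11 and 6 adjusted over the list alone, camera adjusted p = 0.156). These included Atp6v0c, a subunit of the proton pump (0.62 ± 0.115, adjusted p = 0.000505), Npc2, which moves cholesterol out of lysosomes (0.54 ± 0.108, adjusted p = 0.00126), and Cd68 (0.51 ± 0.112, adjusted p = 0.00281).

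Pkm, the pyruvate kinase gene, rose from 999 ± 322 to 2310 ± 520 CPM (adjusted p = 6.77e-07) and Pgk1, of the same pathway, by 0.96 ± 0.142 (SE, adjusted p = 3.12e-05). Of the glycolysis and hypoxia genes 10 of 22 rose and 1 fell (12 and 1 adjusted over the list alone, median 0.461, camera adjusted p = 8.74e-07, adjusted p = 0.148 with an estimated correlation). Of the oxidative phosphorylation genes 17 of 72 rose and 0 fell, before and adjusted over the list alone (median 0.27, camera adjusted p = 6.72e-08, adjusted p = 0.148 with an estimated correlation), with Cox8a at 0.61 ± 0.125 (adjusted p = 0.00137) and Atp5b at 0.42 ± 0.0957 (adjusted p = 0.00349). Of the cytosolic ribosomal proteins 57 of 76 rose (69 adjusted over the list alone, median 0.464, camera adjusted p = 6.37e-24, adjusted p = 0.148 with an estimated correlation), among them Rps6 (0.91 ± 0.129, adjusted p = 1.51e-05). None of 13 mitochondrially encoded mRNAs passed (camera adjusted p = 0.799).

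Several regulators rose with them. The stress genes Atf3 (log2 fold change 2.21 ± 0.221 SE, adjusted p = 8.93e-08) and Gadd45b (3.80 ± 0.397, adjusted p = 9.51e-08), and the phosphatase gene Dusp1 (0.87 ± 0.235, adjusted p = 0.0181), were among 6 of 26 immediate early and dissociation-stress genes that rose, also 6 adjusted over the list alone. That list had a median of 0.326, or 0.263 with genes at 0 reads set to their bound (camera adjusted p = 0.00113, adjusted p = 0.148 with an estimated correlation). Its medians by group were 0.0184 in female WT, 1.02 in female NL4-/-, 0.0396 in male WT and -0.162 in male NL4-/- (camera adjusted p = 0.688, 0.00161, 0.88 and 0.908 with an estimated correlation). Dusp1 did not pass without female NL4-/- control 1 or without male WT control 1. Of the TGF-beta genes 1 of 17 rose and 3 fell (camera adjusted p = 0.518): the inhibitor of transcription Id2 rose by 1.64 ± 0.17 (adjusted p = 9.51e-08) and the signal mediator Smad3 fell by 0.54 ± 0.14 (adjusted p = 0.00951), though not without male NL4-/- control 2. Of the purinergic genes 2 of 20 rose and 4 fell (camera adjusted p = 0.153), with the adenosine receptor Adora2b up from 1.46 ± 2.00 to 13.1 ± 11.1 CPM (adjusted p = 0.00331) and Adora3 down (-0.51 ± 0.123, adjusted p = 0.00577). The proliferation list (1 of 16 rose, camera adjusted p = 0.553) and the unfolded protein response list (2 of 19 rose, camera adjusted p = 0.292) did not pass.

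Summed markers of several other cells were also higher in phagocytosis libraries. These sums, and the CPM of single markers set beside them, are scaled to the library total without TMM normalisation. CPM given by edgeR further on are TMM-normalised. The markers of border-associated macrophages, which live at the brain's surfaces and vessels, summed to 320 ± 113 CPM (SD, n = 16) against 102 ± 30.8 (n = 8, exact permutation test, adjusted p = 0.000416 over 9 marker sets), with 14 of 14 members higher. Most of that sum and of its difference lay in Ms4a6c (123 ± 42.5 against 54.9 ± 23.6 CPM) and Siglec1 (116 ± 55.2 against 31.3 ± 14.2 CPM). The sums for neurons were 109 ± 34.3 against 57.1 ± 15.7 CPM (14 of 16 members higher) and for oligodendrocytes 248 ± 55.8 against 158 ± 27.3 CPM (8 of 15 higher, adjusted p = 0.00073 for both, exact permutation tests). Of the oligodendrocyte genes Mbp was at 63.0 ± 32.0 against 20.9 ± 9.39 CPM and Mag at 36.9 ± 9.25 against 41.9 ± 7.65 CPM. Endothelial (8 of 15 higher, adjusted p = 0.0374) and monocyte (14 of 14 higher, adjusted p = 0.0337) sums were also higher (exact permutation tests). Most of the endothelial difference lay in Pecam1 (29.8 ± 15.1 against 17.3 ± 4.90 CPM). Most of the monocyte difference lay in Fn1 (47.8 ± 36.2 against 29.5 ± 18.5 CPM) and Plac8 (17.9 ± 21.0 against 2.67 ± 2.60 CPM). The edgeR call of Plac8 was lost in 15 of 24 fits with 1 library left out. The lymphocyte sum was lower, 282 ± 90.0 against 392 ± 97.9 CPM (adjusted p = 0.0282, exact permutation test), though 7 of 16 members were higher. Nearly all of that difference lay in the immunoglobulin gene Ighm, at 237 ± 84.5 against 344 ± 89.8 CPM (edgeR log2 fold change -0.56 ± 0.182 SE, adjusted p = 0.0417), whose call was lost in 17 of 24 fits with 1 library left out. The astrocyte (12 of 14 higher, adjusted p = 0.348), neutrophil (7 of 12, 0.140) and erythroid (6 of 7, 0.651) sums did not pass by the exact permutation test. The most abundant astrocyte gene, Slc1a3, was lower in phagocytosis libraries (60.9 ± 13.4 against 89.5 ± 26.1 CPM). So was the most abundant neutrophil gene, Csf3r (407 ± 87.7 against 534 ± 76.6 CPM). These 2 sums therefore do not show that the other members were unchanged. By edgeR, Uchl1, a neuronal deubiquitinase gene, rose from 2.09 ± 1.82 to 32.2 ± 23.4 CPM (adjusted p = 3.16e-07) and the macrophage adhesion gene Siglec1 by 1.84 ± 0.345 (SE, adjusted p = 0.00168). Pf4 had 131 reads against 3, a pooled ratio of 18.8 (95% interval 6.29 to 92.3, adjusted p = 0.00579). Of the astrocyte genes Gfap rose from 1.82 ± 1.57 to 14.1 ± 9.70 CPM (adjusted p = 0.000971) and Aldoc by 2.32 ± 0.647 (adjusted p = 0.0108), while Slc1a3 fell from 94.6 ± 30.8 to 61.0 ± 13.6 CPM (-0.59 ± 0.152, adjusted p = 0.00906), though not without male WT control 2 or male NL4-/- control 1. Cspg4, of oligodendrocyte precursors, rose by 3.57 ± 0.683 (adjusted p = 0.000971), and the neutrophil gene Csf3r fell by 0.46 ± 0.113 (adjusted p = 0.00693).

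By list, the macrophage markers passed with camera (6 of 7 rose, median 2.11, or 1.84 with genes at 0 reads at their bound, adjusted p = 1.31e-05, adjusted p = 0.0908 with an estimated correlation). Neuron markers (2 of 4 rose, adjusted p = 0.00802, adjusted p = 0.11 with an estimated correlation) and oligodendrocyte markers (2 of 5 rose, adjusted p = 0.0127, adjusted p = 0.125 with an estimated correlation) passed as well. The camera adjusted p was 0.153 for astrocyte, 0.607 for endothelial, 0.331 for monocyte, 0.799 for neutrophil and 0.348 for both lymphocyte and erythroid markers.

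**Figure D2:**
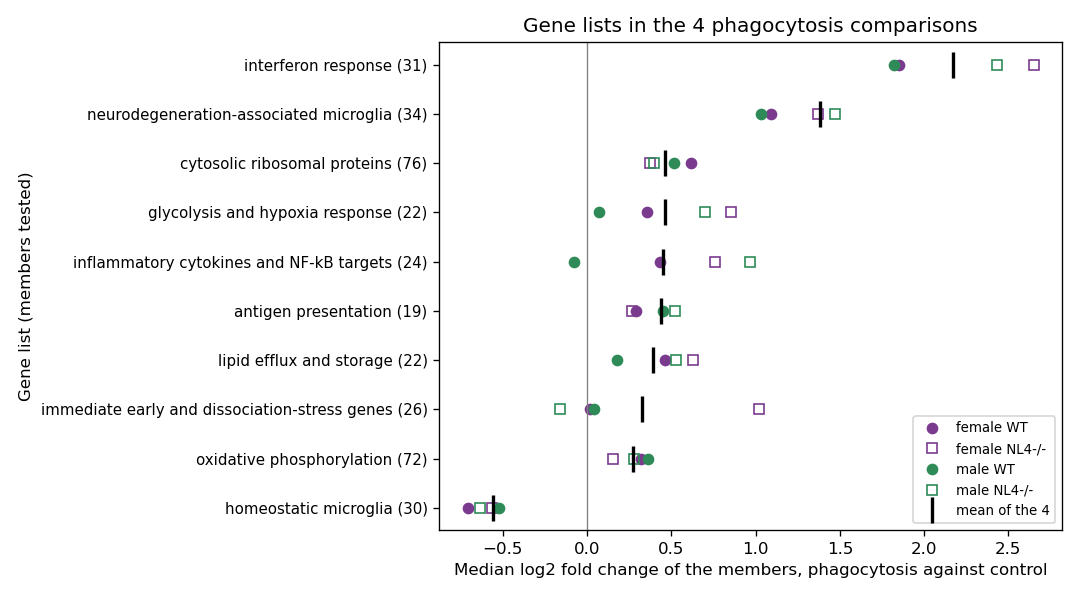
Median log2 fold change between phagocytosis and control of the called gene lists with at least 10 members tested, in each sex and genotype and as the mean of the 4. In the mean the interferon response list was at 2.17 and the homeostatic list at -0.556.

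Within each sex and genotype the same contrast (4 against 2 libraries) asks how the phagocytosis response looked in that group. In female WT, 53 genes rose and 4 fell. Plin2 rose from 65.1 ± 3.38 to 635 ± 113 CPM (log2 fold change 3.28 ± 0.358 SE, edgeR adjusted p = 5.58e-06). Lgals3, the lectin galectin-3, rose from 21.2 ± 16.1 to 418 ± 205 CPM (4.27 ± 0.743, adjusted p = 0.00844), and Vim by 4.54 ± 0.755 (adjusted p = 0.00556). Igf2r, which sorts lysosomal enzymes, had 88 reads against 1, a pooled ratio of 54.4 (95% interval 9.51 to 2170, adjusted p = 0.00139). Rffl fell by 1.69 ± 0.357 (adjusted p = 0.0162) and Rgs2, a brake on G-protein signalling, by 1.23 ± 0.297 (adjusted p = 0.0481). The other genes that fell by the rule were the olfactory receptor genes Olfr365 and Olfr1385. DESeq2 called 274 genes. The edgeR count rested on few libraries: it was 16 without female WT control 1, 1 without female WT control 2, 32 without phagocytosis 2 and 35 without phagocytosis 3, and of 19 named genes only Plin2 passed with every library left out.

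In female NL4-/-, 40 genes rose and 5 fell. Plin2 rose by 3.12 ± 0.37 (SE, edgeR adjusted p = 3.18e-05), and Adam8, a membrane protease gene, rose from 33.5 ± 2.85 to 771 ± 342 CPM (4.51 ± 0.722, adjusted p = 0.00704). Rab7b, of late endosomes, had 199 reads against 1, a pooled ratio of 83.0 (95% interval 14.7 to 3300, adjusted p = 5.05e-05). The hyaluronan receptor gene Cd44 had 174 against 2 reads, a ratio of 36.3 (9.9 to 302, adjusted p = 0.012). Fos, an immediate early transcription factor gene, rose from 15.6 ± 3.01 to 133 ± 22.5 CPM (3.05 ± 0.588, adjusted p = 0.0156) and Dusp1 from 42.6 ± 18.9 to 290 ± 71.9 CPM (2.73 ± 0.543, adjusted p = 0.0211). Uchl1 had 41 reads against 0, at least 5.7-fold (adjusted p = 0.0305). The helicase gene Recql fell by 1.96 ± 0.448 (adjusted p = 0.0355), and the olfactory receptor genes Olfr365, Olfr1385 and Olfr639 fell as well. The immediate early list had a median of 1.02 (camera adjusted p = 1.08e-15, adjusted p = 0.00161 with an estimated correlation), with 4 genes up and 14 adjusted over the list alone. DESeq2 called 178 genes, and the edgeR count of 45 was 3 without control 1, 27 without phagocytosis 1 and 70 without phagocytosis 4; of 23 named genes Plin2 and Rab7b passed throughout.

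In male WT, 31 genes rose and 1 fell. Plin2 rose from 96.4 ± 20.7 to 527 ± 156 CPM (2.46 ± 0.345 SE, edgeR adjusted p = 0.000432), Lgals3 rose by 4.17 ± 0.77 (adjusted p = 0.0196) and Vim by 4.15 ± 0.776 (adjusted p = 0.0196). The scavenger receptor gene Cd36 had 86 reads against 0, at least 10.5-fold (adjusted p = 0.0236), and Rap2b had 78 against 0, at least 9.53-fold (adjusted p = 0.0196). Trpm2, a calcium channel gene, fell from 204 ± 29.0 to 92.4 ± 30.8 CPM (-1.14 ± 0.253, adjusted p = 0.037). DESeq2 called 96 genes. The edgeR count of 32 was 8 without control 1, 0 without control 2 and 58 without phagocytosis 4, and 0 of 12 named genes passed throughout, Plin2 being lost only without male WT control 2, a library with a satellite share of 23.3%.

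In male NL4-/-, 49 genes rose and 10 fell. Plin2 rose by 3.34 ± 0.378 (SE, edgeR adjusted p = 1.19e-05), Ctsb by 1.32 ± 0.21 (adjusted p = 0.00203) and Vim by 5.24 ± 0.884 (adjusted p = 0.00834). Adam8 rose from 37.4 ± 8.85 to 1050 ± 579 CPM (adjusted p = 0.00483), and Cd44 had 178 reads against 1, a pooled ratio of 57.6 (95% interval 10.2 to 2290, adjusted p = 0.0118). The vesicle adaptor gene Ap1s3 fell by 2.12 ± 0.502 (adjusted p = 0.0479) and the DNA repair gene Brca2 by 1.59 ± 0.371 (adjusted p = 0.0375). Gng10 and the olfactory receptor genes Olfr1247, Olfr365 and Olfr1385 fell as well. Chemosensory receptors as a whole took a smaller share of reads in phagocytosis than in control libraries. DESeq2 called 181 genes. The edgeR count of 59 was 1 without control 1, 4 without control 2 and 36 without phagocytosis 1, and of 23 named genes only Plin2 passed throughout.

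Across these 4 comparisons 17 genes passed in every one, all of them up: Cstb, Hmox1, Por, Gadd45b, Ccl4, Glrx, Fth1, Adam8, Vim, Anxa5, Cd72, Plin2, Lgals3, Ftl1, Rab7b, Capg and Lilr4b. Those outside the naming rule were chosen after their values were seen. Hmox1, which breaks down haem, rose by 3.40 ± 0.271 in the mean comparison (SE, edgeR adjusted p = 7.87e-08), the ferritin light chain gene Ftl1 by 1.74 ± 0.158 (adjusted p = 1.39e-08) and the phospholipid-binding gene Anxa5 by 2.89 ± 0.209 (adjusted p = 3.31e-10). Of 92 genes called in at least 1 of the 4, 90 were also called in the mean, which includes them. Across all 9803 genes, which are not independent replicates, the log2 fold changes of pairs of these comparisons had Pearson correlations of 0.343 to 0.445, and 63.9 to 67.1% of genes had the same sign in a pair.

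Camera called 11, 15, 8 and 10 lists in female WT, female NL4-/-, male WT and male NL4-/-, and 2, 3, 2 and 2 of them also passed with an estimated correlation. The neurodegeneration-associated list passed in all 4, with medians of 1.09 (1.03 with genes at 0 reads at their bound), 1.37, 1.03 and 1.47 in that order and adjusted p with an estimated correlation of 0.00408, 0.000903, 0.00241 and 0.000893. In that order 4, 6, 4 and 6 of its genes rose, and 13, 15, 11 and 18 adjusted over the list alone. Its median difference between phagocytosis numbers 1 and 2 and numbers 3 and 4 was 0.0684, 0.936, -0.000948 and -0.118 in that order. Lipid efflux and storage passed in all 4 as well (camera with an estimated correlation, adjusted p = 0.0306, 0.0011, 0.0178 and 0.00255). The homeostatic list had medians of -0.709, -0.565, -0.522 and -0.635, with 0 genes falling in any group and adjusted p = 0.36, 0.24, 0.343 and 0.282 with an estimated correlation. The interferon list had medians of 1.85, 2.65, 1.82 and 2.43 and adjusted p = 0.283, 0.148, 0.278 and 0.282 with an estimated correlation; 3, 13, 0 and 11 of its genes rose adjusted over the list alone.

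NL4-/- was compared with WT within each sex and state, which asks what the loss of neuroligin-4 changed there. In female controls (2 against 2 libraries) no gene passed: the smallest edgeR adjusted p, 0.0599, belonged to 2 immediate early genes. Dusp1 (chromosome 17, 26505590 to 26562128), a phosphatase that switches off MAP kinases, was at 42.6 ± 18.9 CPM in NL4-/- and 471 ± 109 CPM in WT (log2 fold change -3.42 ± 0.588 SE), and Fos (chromosome 12, 85473890 to 85477273) at 15.6 ± 3.01 and 187 ± 14 CPM (-3.53 ± 0.623). The protease gene Adamts1 was at 33.2 ± 10.3 and 113 ± 32.8 CPM (adjusted p = 0.315). Among genes chosen after their values were seen, Egr1 was at 25.1 ± 2.66 and 161 ± 28.2 CPM, Jun at 323 ± 21.6 and 1057 ± 44.5 CPM, and the log2 fold change was -1.59 ± 0.451 for Junb and -1.32 ± 0.328 for Zfp36, an RNA-decay factor gene. In edgeR 0 genes passed, and 210 had an unadjusted p under 0.05 where 490 are expected by chance. DESeq2 called 3: Dusp1 (-3.44, adjusted p = 1.81e-07), Fos (-3.55, adjusted p = 3.84e-06) and mt-Nd4l (-21.18, adjusted p = 0.000199). The mt-Nd4l fold is larger than this depth can measure, and in male controls it was 22, the other way. With female WT control 1, female NL4-/- control 1 or female NL4-/- control 2 left out, edgeR called 1 gene.

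As a group the immediate early and dissociation-stress genes differed in female controls: 25 of 26 had a negative log2 fold change, with a median of -1.31 (camera adjusted p = 2.73e-30, adjusted p = 0.000101 with an estimated correlation). Adjusted over the list alone 11 genes fell, Dusp1 and Fos each with an adjusted p of 0.000159 (edgeR). Mean Fos was 155 ± 66.5 CPM in female WT phagocytosis, 133 ± 22.5 in female NL4-/- phagocytosis, 272 ± 24.8 in male WT control and 279 ± 79.2 in male NL4-/- control, 233 ± 143 in male WT phagocytosis and 169 ± 74.6 in male NL4-/- phagocytosis. Camera also called glycolysis (median -0.39, adjusted p = 3.35e-05, adjusted p = 0.448 with an estimated correlation) and NF-kB genes (-0.288, or -0.271 with genes at 0 reads at their bound, adjusted p = 0.014, adjusted p = 0.735 with an estimated correlation). It called neurodegeneration-associated (-0.241, or -0.249 at the bound, adjusted p = 0.0366, 0.599 with an estimated correlation) and lysosome genes (-0.182, adjusted p = 0.0472, 0.745 with an estimated correlation), and the 2 erythroid markers tested (6.73, or 3.61 at the bound, adjusted p = 0.0477, 0.448 with an estimated correlation). The erythroid score of a library, a mean of log2 CPM over these markers, was 5.125 in NL4-/- control 2 and 1.229 in NL4-/- control 1. It was 0 in both WT controls, so the call rests mainly on 1 library.

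**Figure D3:**
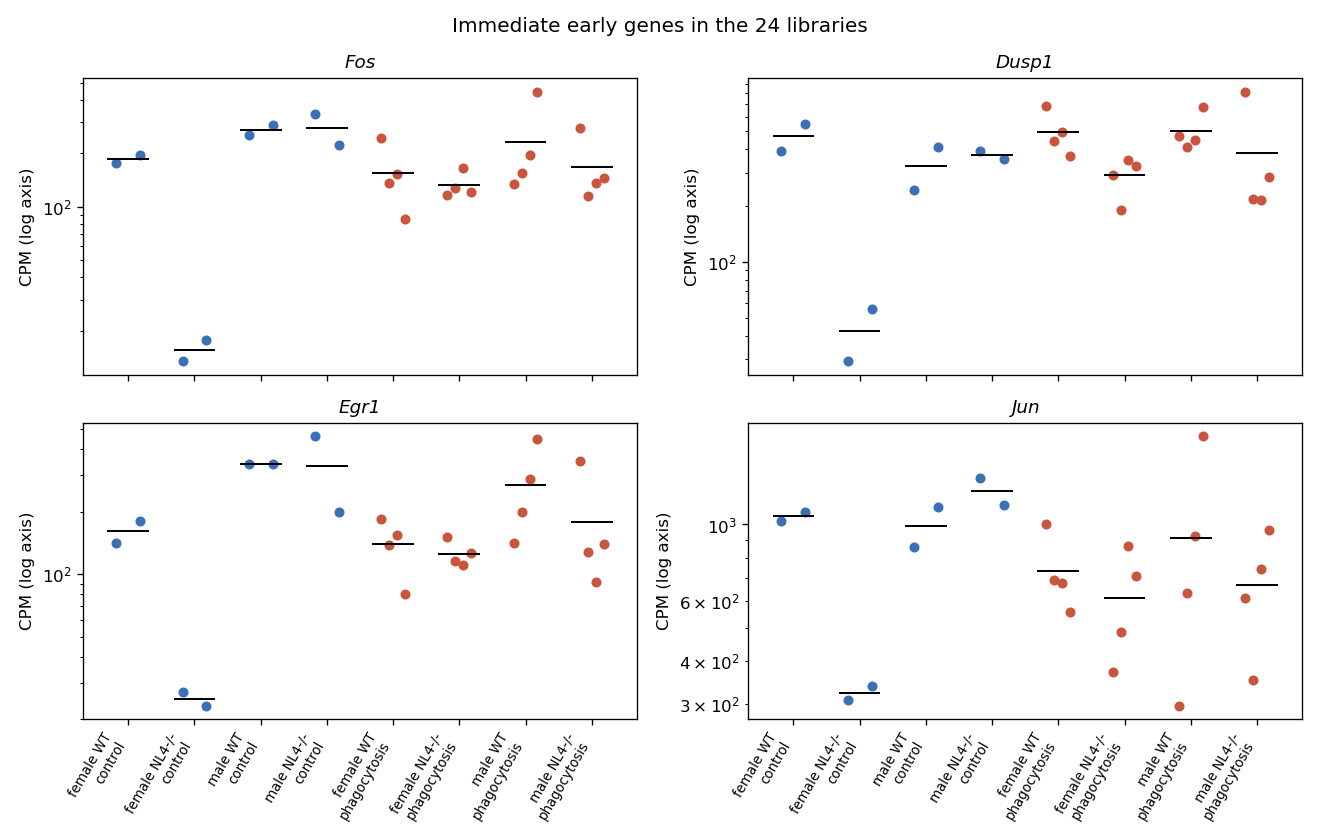
TMM-normalised CPM (log axis) of Fos, Dusp1, Egr1 and Jun in each of the 24 libraries by sex, genotype and state, with a point per library and a line at each group mean. The 2 female NL4-/- controls had a mean Fos of 15.6 CPM, against 133 to 279 CPM in the other groups.

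In female phagocytosis libraries (4 against 4) no gene passed for genotype. Uchl1 was at 15.4 ± 6.44 CPM in NL4-/- and 55.2 ± 32.6 CPM in WT (log2 fold change -1.86 ± 0.438 SE, edgeR adjusted p = 0.938), the splicing-related gene Pnisr had -0.86 ± 0.216 and the fatty acid oxidation gene Eci1 had -1.10 ± 0.281. In edgeR 0 genes passed and 510 had an unadjusted p under 0.05. DESeq2 called 3, Gm10222 (log2 fold change 23.55), mt-Co2 (22.59) and Gm16867 (6.045). The first 2 folds are larger than this depth can measure. Camera called ribosomal proteins (median -0.208, adjusted p = 1.17e-07), oxidative phosphorylation (-0.144, adjusted p = 0.00175) and immediate early genes (-0.215, adjusted p = 0.00252), with adjusted p = 0.906, 0.906 and 0.689 with an estimated correlation. In this comparison 1 immediate early gene fell adjusted over the list alone.

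In male controls (2 against 2) no gene passed for genotype. Cd83, a surface marker of activated antigen-presenting cells, was at 121 ± 4.45 CPM in NL4-/- and 513 ± 230 CPM in WT (log2 fold change -2.09 ± 0.404 SE, edgeR adjusted p = 0.205), and the mitochondrial carrier gene Ucp2 at 713 ± 43.3 and 1411 ± 214 CPM (adjusted p = 0.673). The NF-kB inhibitor genes Tnfaip3 and Nfkbia had -2.76 ± 0.733 and -1.37 ± 0.413. In edgeR 0 genes passed and 328 had an unadjusted p under 0.05. DESeq2 called 5: Cd83 (adjusted p = 0.00287), Ucp2 (adjusted p = 0.0117), mt-Nd4l, Gm48128 and Gm10222. The log2 folds of mt-Nd4l (22), Gm48128 (-23.05) and Gm10222 (-20.96) are larger than this depth can measure. Without male WT control 1 edgeR called 2. Camera called NF-kB genes (median -1.09, or -1.05 at the bound, adjusted p = 6.66e-14, 0.156 with an estimated correlation), of which 5 fell adjusted over the list alone, glycolysis (-0.574, adjusted p = 9.94e-10, 0.177 with an estimated correlation) and interferon response (-0.919, adjusted p = 6.44e-08, 0.445 with an estimated correlation). The other calls were uptake (-0.132, or -0.139 at the bound, adjusted p = 0.0417), proliferation (0.408, adjusted p = 0.00119), macrophage (-1.51, or -0.632 with 2 of the 7 at their bound, adjusted p = 0.0417) and neutrophil markers (-1.44, or -1.29 at the bound, adjusted p = 0.0224), each with adjusted p = 0.403 with an estimated correlation, and ribosomal proteins (0.139, adjusted p = 0.00656, 0.805 with an estimated correlation).

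In male phagocytosis libraries (4 against 4) no gene passed for genotype. Gnpda1, an enzyme of amino sugar breakdown, was at 39.2 ± 7.02 CPM in NL4-/- and 90.7 ± 18.6 CPM in WT (log2 fold change -1.20 ± 0.256 SE, edgeR adjusted p = 0.532), and Slc7a1, a carrier of arginine and lysine, at 100 ± 27.3 and 41.5 ± 14.6 CPM (1.26 ± 0.282, adjusted p = 0.532). In edgeR 0 genes passed, 465 had an unadjusted p under 0.05, and DESeq2 called 0. Camera called interferon response (median -0.462), NF-kB (-0.605, adjusted p = 0.00012 for both) and proliferation genes (0.29, adjusted p = 0.0314), each with adjusted p = 0.974 with an estimated correlation. Across genes, which are not independent replicates, genotype fold changes in females and males had a Pearson correlation of -0.0295 in controls and 0.0173 in phagocytosis libraries, and between states 0.131 in females and -0.0327 in males. The median SE of a log2 fold change was 0.47 in female and 0.502 in male controls, and 0.337 and 0.334 in phagocytosis libraries. In simulated counts with a 2-fold difference 7 of 100 genes were recovered in female controls and 43 in female phagocytosis libraries. Most simulated differences of that size were thus missed by this fit. The simulation drew genes independently and without structure among libraries, so recovery in the real libraries may differ. In the real female controls 210 genes had an unadjusted edgeR p under 0.05, fewer than the 490 expected by chance.

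Males were compared with females within each genotype and state. In WT controls no gene passed: Cd83 was at 513 ± 230 CPM in males and 161 ± 10.6 CPM in females (log2 fold change 1.67 ± 0.385 SE, edgeR adjusted p = 0.6). By edgeR 0 genes passed and 332 had an unadjusted p under 0.05; DESeq2 called 1, and edgeR called 1 without female WT control 1. Camera called NF-kB (median 0.741, adjusted p = 8.63e-07), interferon (0.554, adjusted p = 0.00225) and glycolysis genes (0.25, adjusted p = 0.00559), with adjusted p = 0.864, 0.95 and 0.864 with an estimated correlation. In WT phagocytosis the Y-linked Eif2s3y (54 reads against 0, adjusted p = 0.00488) and the X-linked Gm26992 (1 read against 52, adjusted p = 0.00488) passed; DESeq2 called 4. The count was 0 without female WT phagocytosis 1. Camera called interferon (0.462, adjusted p = 0.032), NF-kB (0.381, adjusted p = 0.00613) and ribosomal protein genes (-0.2, adjusted p = 1.48e-06), each with adjusted p = 0.974 with an estimated correlation.

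In NL4-/- controls Fos was the 1 gene that passed, at 279 ± 79.2 CPM in males and 15.6 ± 3.01 CPM in females (log2 fold change 4.11 ± 0.629 SE, edgeR adjusted p = 0.017). Egr1 was at 330 ± 185 and 25.1 ± 2.66 CPM (adjusted p = 0.0916) and Dusp1 at 373 ± 25.4 and 42.6 ± 18.9 CPM (adjusted p = 0.104). Fos had an adjusted p of 0.301 without female control 1, 0.237 without female control 2, 0.29 without male control 1 and passed without male control 2. It did not pass with the replicate number as a replicate block, with the number pair as a covariate, or without the 3 libraries over 20% satellite-like. The count was 0 without male NL4-/- control 1 and 2 without male NL4-/- control 2. DESeq2 called 11. The immediate early list had a median of 1.66 (camera adjusted p = 2.78e-36, adjusted p = 3.19e-05 with an estimated correlation), with 1 gene up and 9 adjusted over the list alone. In NL4-/- phagocytosis the 1 gene called was Gm26992 (0 reads against 52, adjusted p = 0.00358), DESeq2 called 2, and camera called oxidative phosphorylation (median 0.136, adjusted p = 0.000241, 0.887 with an estimated correlation).

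The genotype by sex interaction, the subject of the series title, asks whether the knockout's effect differed between sexes. In controls no gene passed: Dusp1 had an interaction of 3.60 ± 0.774 (log2, SE) and Fos of 3.57 ± 0.796 (edgeR adjusted p = 0.65 for both), with both genes lower in NL4-/- than in WT females. By edgeR 0 genes passed and 239 had an unadjusted p under 0.05; DESeq2 called 3. The count was 1 without female WT control 1, female NL4-/- control 1 or female NL4-/- control 2. The immediate early list passed (median 0.919, camera adjusted p = 2.47e-18, adjusted p = 0.00186 with an estimated correlation), with 5 genes adjusted over the list alone. Camera also called NF-kB (-0.521, adjusted p = 0.00201), interferon (-0.622, adjusted p = 0.0146) and neutrophil genes (adjusted p = 0.00526), with adjusted p = 0.86, 0.86 and 0.352 with an estimated correlation. In phagocytosis libraries no gene passed: Gnpda1 had -1.35 ± 0.358 and Zfp956 -2.42 ± 0.61 (adjusted p = 0.977). By edgeR 0 genes passed, 467 had an unadjusted p under 0.05 and DESeq2 called 2. Camera called ribosomal proteins (0.271, adjusted p = 1.77e-07), oxidative phosphorylation (0.119, adjusted p = 0.0118), interferon (-0.478) and NF-kB genes (-0.416, adjusted p = 0.027 for both), each with adjusted p = 0.913 with an estimated correlation.

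The phagocytosis response was compared between genotypes and between sexes by 4 further interactions, and no gene passed in any. Between genotypes in females Fos had 3.30 ± 0.716 (log2, SE, edgeR adjusted p = 1); 252 genes had an unadjusted p under 0.05, DESeq2 called 1, and edgeR called 1 without female WT control 1, female NL4-/- control 1 or female NL4-/- control 2. The immediate early list passed there (median 0.924, camera adjusted p = 4.62e-12, adjusted p = 0.0144 with an estimated correlation, 8 genes adjusted over the list alone), as did ribosomal proteins (-0.272, adjusted p = 6.91e-06, 0.813 with an estimated correlation) and erythroid markers (adjusted p = 0.0206, 0.456 with an estimated correlation). The erythroid score was 8.559 in female WT phagocytosis 1 and 1.695 to 4.433 in the rest of that group. Between genotypes in males Fbxo9 had 2.47 ± 0.635; 246 genes had an unadjusted p under 0.05 and DESeq2 called 0. Camera called NF-kB (0.796, adjusted p = 0.00053) and glycolysis genes (0.477, adjusted p = 0.000182), both with adjusted p = 0.619 with an estimated correlation. Between sexes in WT Ankhd1 had -1.60; 240 genes had an unadjusted p under 0.05, DESeq2 called 0, edgeR called 1 without female WT control 1, and no list passed.

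Between sexes in NL4-/- Fos had an interaction of -3.78 ± 0.719 (log2, SE, edgeR adjusted p = 0.313), Egr1 -3.23 and Dusp1 -2.69. By edgeR 0 genes passed, 167 had an unadjusted p under 0.05 and DESeq2 called 5. The count was 1 without female NL4-/- control 1 or female NL4-/- control 2 and 3 without male NL4-/- phagocytosis 1. The immediate early list passed (median -1.47, camera adjusted p = 3.82e-20, adjusted p = 0.00106 with an estimated correlation, 8 genes adjusted over the list alone). The same 2 female NL4-/- controls enter every contrast in which this list passed with an estimated correlation, which therefore are not separate observations: genotype and sex in controls, phagocytosis in female NL4-/-, and the 3 interactions.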

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

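The splits of the libraries were planned; the tests of immediate early genes, of number pairs, of satellite shares and of marker sets were chosen only after the results were seen.

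The immediate early and dissociation-stress list was singled out because its genotype and state effects differed between groups by a test of the difference itself: the camera adjusted p with an estimated correlation was 0.00186 for genotype by sex in controls, 0.0144 for genotype by phagocytosis in females and 0.00106 for sex by phagocytosis in NL4-/-. Fos, Dusp1 and Egr1 were low in the 2 female NL4-/- controls, which enter all 3 tests. Unequal satellite shares are argued against, since the list's median in female controls was -1.31 with the satellite share as a covariate (camera p = 1.09e-06 with an estimated correlation), and so is 1 aberrant library, since the median closest to 0 with any of the 4 female controls left out was -1.28 and the largest camera p was 0.000175. A genotype difference of equal size in both states is argued against as well, since the median was -1.31 in female controls and -0.215 in female phagocytosis libraries (camera p = 0.0511 with an estimated correlation) and the interaction had a median of 0.924 (p = 0.000533), although this interaction also helped to single the list out. The highest list score of the 2 libraries was 5.034 and the lowest of the other 22 was 5.923; handling or isolation on separate days could give this and cannot be told apart from a biological difference of that group, because the labels give no day and the group has 2 libraries.

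Between phagocytosis libraries numbered 1 and 2 and those numbered 3 and 4, edgeR called 153 genes in NL4-/- of both sexes together (4 against 4 libraries, 66 higher and 87 lower in numbers 1 and 2), 39 in NL4-/- females and 2 in NL4-/- males alone, 1 in WT males, 0 in WT females (570 at an unadjusted p under 0.05) and 0 in WT together (837), and DESeq2 was not run on these contrasts. Over all 4 groups together edgeR called 130 genes, 33 higher and 97 lower in numbers 1 and 2. The contrast was chosen after this parting gave the most genes, 121, of 35 splits of the NL4-/- phagocytosis libraries. Counts and p-values that include NL4-/- libraries are therefore not a separate test of it. The WT libraries were not in those splits. In NL4-/- P2ry12, a purinergic receptor of resting microglia, was at 321 ± 120 against 1181 ± 102 CPM (log2 fold change -1.88 ± 0.265 SE, adjusted p = 0.00082). The homeostatic list had a median of -0.817 in NL4-/- females, -0.576 in NL4-/- males, -0.575 in WT males and -0.0136 in WT females, and the interferon list 1.69, 1.31, 0.878 and -0.383 in that order (camera adjusted p with an estimated correlation 0.0326 and 0.0568 in NL4-/- together, 0.0425 and 0.132 over all 4 groups together, and at least 0.0606 in each group alone). Unequal satellite shares (8.05% ± 6.08 against 5.16% ± 2.95, SD, in NL4-/-) are argued against, since 152 genes passed with the share as a covariate, 137 of them also without it. Of the 153 genes 127 had the same sign in WT, but with smaller medians (-0.30 in WT against -1.04 for the lower genes, 0.11 against 1.10 for the higher), and 1 gene passed for the difference between genotypes (714 at an unadjusted p under 0.05), so handling or sequencing on separate occasions could explain the pattern and cannot be told apart from a state of the animals, because the numbers are not dated.

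Markers of border-associated macrophages and of neurons were higher in phagocytosis libraries. Their CPM here are scaled to the library total without TMM normalisation. For the neuronal gene Uchl1, neuronal RNA as the source is argued against: 8 other neuronal transcripts (Snap25, Syt1, Stmn2, Nefl, Nefm, Tubb3, Syn1 and Map2) together differed by 4.6 CPM (SE 1.84; exact permutation p = 0.0511), against 30.4 CPM for Uchl1 alone. The 8 macrophage markers Mrc1, Cd163, Lyve1, Pf4, F13a1, Cbr2, Folr2 and Cd209f summed to 61.6 ± 44.1 CPM against 10.3 ± 4.30 in controls (SD, 16 and 8 libraries; exact permutation p = 0.00366). Over the 16 phagocytosis libraries their mean pairwise Spearman correlation was 0.4536 (permutation p = 0.0001, the smallest that 10000 resamples can give, and also 0.0001 with libraries exchanged only within group and number pair, where resamples averaged 0.2238), so a few such macrophages among the sorted cells are a candidate source. How many of them the sort for Fcrls would remove was not tested. Expression of these genes by microglia themselves stays open.

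Other splits of the same libraries were counted for each contrast with at least 4 libraries on each side. Chance is argued against for phagocytosis against control, where 1332 genes passed in the real split, the highest other split gave 9, and 1 of 100 splits, the real one, gave as many. These splits were a random sample of those possible within sex and genotype, so no share below 1 of 100 could be seen. From the number of genes alone chance cannot be excluded for sex in WT phagocytosis (2 of 35 splits, real 2, highest other 3) or in NL4-/- phagocytosis (6 of 35, real 1, highest other 121). The genes called there, Eif2s3y and Gm26992, lie on Y and X. Reads of Ddx3y and Eif2s3y parted every male from every female library, so for Eif2s3y chance is not at issue. That does not cover Gm26992, which had 1 read in males against 52 in females in WT, and 0 against 52 in NL4-/-, in separate libraries. Where the real count was 0 any split gives as many, so the count says nothing: genotype in female phagocytosis (35 of 35; highest other 1), in male phagocytosis (35 of 35; highest other 4) and genotype by sex in phagocytosis (100 of 100; highest other 65). The split with 121 genes parted numbers 1 and 2 from 3 and 4 in both sexes, which points to a structure of the samples.

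Each library measure and list score was checked in each of the 4 phagocytosis groups, 132 checks in all. In 8 of them 1 library lay far from the other 3, where chance gives about 1 in 20, or 7, if checks are independent. They are not, since measures such as the ribosomal protein share and the ribosomal list score overlap. Male WT phagocytosis 1 had 4.908% of its reads on ribosomal protein genes (others 3.138 to 3.329), a ribosomal list score of 8.994 (others 8.296 to 8.362) and an endothelial score of 1.477 (others 4.096 to 4.406). Male NL4-/- phagocytosis 2 had 3.561% on ribosomal protein genes (others 3.912 to 3.923). Female WT phagocytosis 2 had a lipid efflux score of 6.089 (others 6.439 to 6.47), and female WT phagocytosis 3 a proliferation score of 4.56 (others 5.029 to 5.052). Male WT phagocytosis 3 had a border-associated macrophage score of 2.921 (others 4.53 to 4.762), and female NL4-/- phagocytosis 4 a mitochondrial mRNA score of 6.796 (others 4.626 to 4.789).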

How the results depend on the processing

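Of the named genes that passed in the mean phagocytosis comparison, 82 of 82 also passed with RLE size factors, with DESeq2 and with satellite-like genes left out, 79 with no filter, 78 with the 5 CPM filter, 69 with length-scaled counts, 69 with the satellite covariate, 70 with phagocytosis numbers 3 and 4 alone and 53 without the 3 libraries over 20% satellite-like; none reversed. The 19 counts of genes stayed within 1.5 times with RLE size factors and with satellite-like genes left out. The satellite and number alternatives were chosen after seeing the data. Other counts moved as follows, and the cause was not tested unless said.

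With no filter, counts for genotype were 11 and 19 in female control and phagocytosis and 8 and 7 in male; for phagocytosis 269 and 176 in female WT and NL4-/- and 99 and 160 in male; for sex 12 and 29 in WT control and phagocytosis and 11 and 9 in NL4-/-; for genotype by sex 9 and 5 in control and phagocytosis; for genotype by phagocytosis 7 and 2 in females and males; for sex by phagocytosis 1 and 5 in WT and NL4-/-. With length-scaled counts they were 1 for genotype in female controls, 33 and 19 for phagocytosis in female and male WT, and 0 and 3 for sex in WT phagocytosis and NL4-/- control. With only the groups compared they were 25, 1 and 9 for genotype in female control, female phagocytosis and male control, 184, 25, 18 and 119 for phagocytosis in female WT, female NL4-/-, male WT and male NL4-/-, 27, 0 and 18 for sex in WT control, WT phagocytosis and NL4-/- control, and 10, 3 and 1 for genotype by sex in controls, genotype by phagocytosis in females and sex by phagocytosis in NL4-/-; the spread then comes from as few as 2 libraries per group. DESeq2 gave 3, 3 and 5 for the same genotype comparisons, 274, 178, 96 and 181 for phagocytosis, 1, 4, 11 and 2 for sex, 3 and 2 for genotype by sex, 1 for genotype by phagocytosis in females and 5 for sex by phagocytosis in NL4-/-.

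With the satellite covariate, counts were 1 for genotype in female and 1 in male controls, 29 and 22 for phagocytosis in female and male NL4-/-, and 5 for sex in NL4-/- control. Without the 3 libraries over 20% satellite-like, which leaves 1 control in 3 groups, they were 1 for genotype in female controls, 3, 0 and 1 for phagocytosis in female NL4-/-, male WT and male NL4-/-, 410 for the mean, and 1 for each of genotype by sex in controls, genotype by phagocytosis in females and sex by phagocytosis in NL4-/-. With phagocytosis numbers 3 and 4 only, the mean count was 782. With the number pair as a covariate, counts were 99 for phagocytosis in female WT and 0 for sex in NL4-/- control. Without genes on X and Y, sex in WT and NL4-/- phagocytosis gave 0 and 0. With the 5 CPM filter, sex in NL4-/- phagocytosis gave 2, the phagocytosis correlations across genes were 0.339, 0.299, 0.313, 0.307, 0.344 and 0.237, and the genotype ones were -0.00382 between sexes in controls and 0.087 between states in females.

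With the replicate block, phagocytosis counts were 293, 104, 61 and 167 in female WT, female NL4-/-, male WT and male NL4-/-, and sex in NL4-/- control gave 0; numbers 3 and 4 have no control of the same number, and the cause was not tested. Correlations of libraries by number lay between -0.141 and 0.176, so the numbers were not read as pairs.

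Leaving out 1 library at a time, where a lone control is assumed to vary like the other groups, genotype counts ran from 0 to 1 in female controls, 0 to 0 in female phagocytosis, 0 to 2 in male controls and 0 to 0 in male phagocytosis. Phagocytosis counts ran from 1 to 64 in female WT, 3 to 70 in female NL4-/-, 0 to 58 in male WT, 1 to 55 in male NL4-/- and 781 to 1508 in the mean. Sex counts ran from 0 to 1 in WT control, 0 to 3 in WT phagocytosis, 0 to 2 in NL4-/- control and 1 to 1 in NL4-/- phagocytosis. Interaction counts ran from 0 to 1 and 0 to 0 for genotype by sex in control and phagocytosis, 0 to 1 and 0 to 0 for genotype by phagocytosis in females and males, and 0 to 1 and 0 to 3 for sex by phagocytosis in WT and NL4-/-. Of 513 list results 83 no longer passed with an estimated correlation, 70 no longer passed and 3 newly passed with fry, and 7 and 8 with the replicate block. Depth limits genes under about 10 CPM, which have few reads in a library.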

Other observations

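Both tests here were chosen only after the results were seen.

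Among the 17 genes that rose in all 4 phagocytosis comparisons, Hmox1, Fth1 and Ftl1 handle haem and iron, and Glrx keeps proteins reduced; several are targets of NRF2, the transcription factor of the oxidative stress response. A hypothesis is that NRF2 targets and iron handling genes rise as a group in phagocytosis libraries, and that proteasome subunits rise with them. Of 24 members of an added NRF2 and iron list that were not among the 17 or otherwise named, 11 rose and 21 had a positive log2 fold change (median 0.55; camera p = 0.00113 with an estimated correlation) in the mean comparison. The haem transporter gene Slc48a1 rose by 1.33 ± 0.155 (SE; edgeR adjusted p = 5.45e-07) and the peroxiredoxin gene Prdx1 by 0.99 ± 0.135 (adjusted p = 8.09e-06). Of 36 proteasome subunits tested in the same way 24 rose and 35 were positive (median 0.451; camera p = 0.00231 with an estimated correlation); Psmd3 rose by 1.30 ± 0.172 (adjusted p = 6.65e-06). Both results are consistent with the hypothesis, but the lists were chosen on these libraries, and what was taken up is not given, so a load of haem or iron from the material taken up was not tested.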
